A study of Mus musculus with 2 samples.

How the data were processed

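ChIP-seq was carried out on HC11 cells with a custom antibody against mouse Ovol2 and with a control IgG, 1 library each. Per the labels' protocols, cells were scraped and sonicated, and libraries were made with a commercial ChIP-seq kit and 16 cycles of PCR. Per the submitters' processing notes, the reads were handled with Bowtie 0.12.8, SAMtools 0.1.18 and bedtools 2.15.0, and the genome build was mm9; the notes as used here give these tools no role or order.

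The authors deposited a list of regions for each library. The Ovol2 list gives chromosome, start and end alone, with no score, height or p-value per region, and is not sorted by position. Its caller and threshold and whether the IgG library served as its control are not given in the sources used here; its name speaks of an FDR of 5%. The IgG list also holds a score per region deposited by the authors, and its regions are named as peaks of MACS. No header names the scale of this score, whose values run from 50.01 to 3100, so it was used only to rank IgG regions within their own list. The lists may have been called with different settings, which would change the number and the length of regions, and the duplicate handling and fragment length behind them are not given in the sources used here. Without read counts, no signal could be compared between libraries, and precision is limited by the number of regions.

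All coordinates are printed 1-based in mm9. A region counted as shared when it overlapped a region of the other list by at least 1 bp. The overlap was set against 1000 random placements of the Ovol2 regions, each on its own chromosome and with its own length, between the first and the last region called there in either list. Counts per chromosome were compared between lists by Fisher's exact test, and with the span of the chromosome by an exact binomial test, with Benjamini-Hochberg adjustment. Median lengths were compared by permutation of regions, with 10000 permutations per chromosome and 100000 for shared against other regions. Proportions carry exact (Clopper-Pearson) 95% intervals, except that a count of 0 for a bin is given with the limit of 3 counts over the list. The design, most alternatives and the rule for naming regions were set before the data were examined; the closing section names the alternatives added later. That rule named the 10 highest-ranked Ovol2 regions outside IgG regions, the 5 highest-ranked shared ones and the 5 IgG regions of highest score, ranking by length where a list had no score. The sixth shared region, the dense bins, the first 4 Mb, the clustering of neighbours and the length by chromosome and by bin of 10 Mb were chosen after the data were seen.

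In simulated lists of 1338 regions with the real lengths, 0, 6 and 50 regions planted on IgG regions were counted as 0, 6 and 51. The length test called 20 of 20 simulated sets of 40 regions made 1.3 times longer, and 1 of 20 sets left as they were. Sets as small as the 6 shared regions were not simulated, so these runs do not show the power of that comparison. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.

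No mm9 sequence or annotation was used here, and the gene table at hand refers to GRCm38. Regions were therefore not assigned to genes, exons or start sites, and 3 planned tests were not run: the distance to transcription start sites, the recognition hexamer of Ovo proteins, and the 7 gene lists fixed beforehand. The comparison planned on scores of Ovol2 regions was made on their lengths, because that list has no score.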

Results

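Genomic regions recovered with an antibody against Ovol2 were compared with regions called for a control IgG in HC11 cells. HC11 is a mouse mammary epithelial cell line of BALB/c origin, and Ovol2 is a zinc finger transcription factor of epithelial cells. Chromatin immunoprecipitation followed by sequencing (ChIP-seq) gave 1 library per antibody, from untreated cells at passages 4 to 7. The Ovol2 list held 1338 regions and the IgG list 1045 regions, in mm9 coordinates. Because there was no replicate of either antibody, every p-value below describes how regions lie within these 2 lists and does not measure variation between cultures. The depth of the libraries is unknown, since the lists give no read counts, and the intervals cover counting error only.

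The comparison of antibodies asks which places in the genome were called with the Ovol2 antibody and not with the control antibody. The 1338 Ovol2 regions lay on the 19 autosomes and X and covered 1.25 Mb in all. Their median length was 887 bp, with an interquartile range of 742 to 1079 bp. The IgG regions were much shorter, with a median of 125 bp and an interquartile range of 107 to 138 bp, and covered 0.174 Mb. The ratio of the medians was 7.10. A length of at least 500 bp was found for 1279 Ovol2 regions, or 95.6% (exact binomial 95% interval 94.4 to 96.6%), and for 24 IgG regions, or 2.30% (1.48 to 3.40%). How each list was called and filtered is only partly given in the sources used here, and the lists may have been called with different settings.

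**Figure D1:**
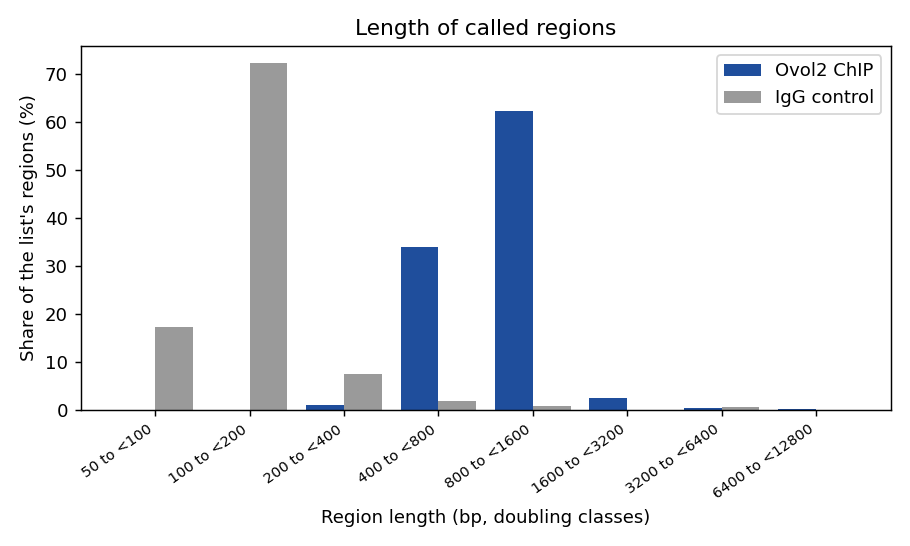
Share of regions (vertical axis, percent of each list) in classes of region length (horizontal axis, bp), for the Ovol2 ChIP (blue) and the IgG control (grey), 1 library each. Of the Ovol2 regions, 62.3% were from 800 to under 1600 bp long, and of the IgG regions 72.3% were from 100 to under 200 bp long.

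The 2 lists had almost no region in common. Of the Ovol2 regions, 6 overlapped an IgG region by at least 1 bp, or 0.448% (exact binomial 95% interval 0.165 to 0.974%), and 1332 regions, or 99.6% (99.03 to 99.84%), lay outside every IgG region. Whether the IgG library served as a control or filter for the Ovol2 list is not known. If it did, a small overlap would follow from the calling, so this share does not measure the specificity of the antibody. The 6 shared regions were more than random placement gave on average. Placement was even over the span of each chromosome, without regard to where regions can be called. The excess is thus measured against even placement only, which may overstate it. When the Ovol2 regions were placed at random on their own chromosomes 1000 times, a mean of 0.618 regions overlapped an IgG region, with a maximum of 6 (9.71-fold, one-sided permutation p = 0.002). Among the 671 longest Ovol2 regions 2 were shared (5.42-fold, permutation p = 0.058). A rule that at least 50% of the Ovol2 region be covered could not test the excess, because IgG regions are short and random placement then gave a mean of 0.024 (0 shared). Of the 100 IgG regions with the highest scores, 1 overlapped an Ovol2 region (1%, exact binomial 95% interval 0.0253 to 5.45%).

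The longest shared region lay on chromosome 4 from 43506171 to 43507529 (1359 bp) and contained an IgG region of 107 bp with a score of 55.89. The shared region on chromosome 5 from 147071973 to 147073213 (1241 bp) contained the shared IgG region with the highest score, 481.73. The other shared Ovol2 regions lay on chromosome 1 from 33956713 to 33957575, on chromosome 6 from 136752483 to 136753332, on chromosome 9 from 36575022 to 36575860 and on chromosome 10 from 11211889 to 11212173. The IgG regions covered between 7.87% and 36.5% of the shared Ovol2 regions. Shared Ovol2 regions had a median length of 856.5 bp against 887 bp for the rest, a difference within the spread of regions (two-sided permutation test, p = 0.803). The 6 shared IgG regions had a median score of 64.5 against 59.97 for the other IgG regions (two-sided permutation test, p = 0.455).

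Among Ovol2 regions outside IgG regions, the longest spanned 8620 bp on chromosome 1, from 90169001 to 90177620. The next 7 in length were all on chromosome 11. They were the regions from 113542342 to 113547400 (5059 bp), 120477976 to 120481850 (3875 bp), 120491143 to 120494603 (3461 bp), 110196710 to 110200147 (3438 bp), 120503299 to 120506429 (3131 bp), 121683909 to 121686566 (2658 bp) and 109855279 to 109857896 (2618 bp). The remaining regions among the 10 longest lay on chromosome 5 from 5253266 to 5255741 (2476 bp) and on chromosome 9 from 13630372 to 13632807 (2436 bp). An IgG region lay 3.31 kb from the chromosome 11 region that starts at 120491143, and 5.18 kb from the one that starts at 120503299.

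The highest IgG scores belonged to regions without a nearby Ovol2 region. Scores of 3100, the maximum of the list, were given to a 992 bp region on chromosome 15 (74916498 to 74917489) and a 470 bp region on chromosome 9 (35112726 to 35113195). The nearest Ovol2 regions were 811 kb and 187 kb away. A region on chromosome 2 (98502371 to 98503166) had a score of 2783.2, and a second on the same chromosome (98506386 to 98507510) had 2752.71. The mitochondrial genome held 2 IgG regions, of which the one from 10925 to 15687 scored 2753.83, and no Ovol2 region. The median IgG score was 60.0, and the lowest 50.01.

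The lists were distributed differently over the chromosomes. Chromosome 7 held 95 Ovol2 regions (7.10% of the list) and 14 IgG regions (1.34%). Chromosome 8 held 72 Ovol2 regions (5.38%) and 114 IgG regions (10.9%), and chromosome 9 held 73 (5.46%) and 112 (10.7%). In all, 7 of the 22 chromosomes differed between the lists after Benjamini-Hochberg adjustment of Fisher's exact tests (two-sided). The Ovol2 share was higher on chromosomes 2, 7 and 13, with adjusted p = 0.0214, 3.49e-11 and 0.0273 (Fisher's exact test). It was lower on chromosomes 6, 8, 9 and Y, with adjusted p = 0.00955, 7.79e-06, 1.62e-05 and 0.000117 (Fisher's exact test). When regions within 100 kb of each other were counted once, 4 chromosomes differed, and chromosomes 9, 13 and Y no longer did (Fisher's exact test, adjusted p = 0.956, 0.185 and 0.684). The Ovol2 minus IgG share went from -5.26 to -0.327 percentage points on chromosome 9 and from -1.24 to -0.127 on Y, but only from 1.96 to 1.73 on chromosome 13, where fewer regions were counted.

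Relative to chromosome span, Ovol2 regions were frequent on chromosome 11 and scarce on X. The span was measured from the first to the last region called on a chromosome in either list. Chromosome 11 held 101 Ovol2 regions against 62.7 expected (exact binomial test, adjusted p = 3.95e-05 over 20 chromosomes), and X held 30 against 85.5 (adjusted p = 4.93e-11). IgG regions also exceeded span on chromosome 11, with 65 against 48.3 expected (exact binomial adjusted p = 0.0299). With regions within 100 kb counted once, they numbered 50 against 36.9 (exact binomial adjusted p = 0.0686). The share of chromosome 11 did not differ between the lists (Fisher's exact test, adjusted p = 0.308). Chromosome 19 held 47 against 30.4 expected (exact binomial adjusted p = 0.0285), and 36 against 26.4 when regions within 100 kb were counted once, which missed the threshold with fewer regions (adjusted p = 0.301). IgG regions departed from span on 12 of the 20 chromosomes, and on 8 when regions within 100 kb were counted once. They too were scarce on X, with 39 against 65.8 expected (exact binomial adjusted p = 0.00114), or 17 against 50.3 when regions within 100 kb were counted once (adjusted p = 4.95e-07), and chromosome 7 held 14 against 60.3 (adjusted p = 3.63e-12). Chromosomes 2 and 13 held 48 IgG regions against 72.1 and 24 against 47.6 (exact binomial adjusted p = 0.00497 and 0.000823). Ovol2 regions did not depart from span on chromosomes 2, 7 and 13, with 98 against 93.7, 95 against 78.4 and 57 against 61.8 (exact binomial adjusted p = 0.741, 0.273 and 0.741). The higher Ovol2 shares there thus went with few IgG regions.

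**Figure D2:**
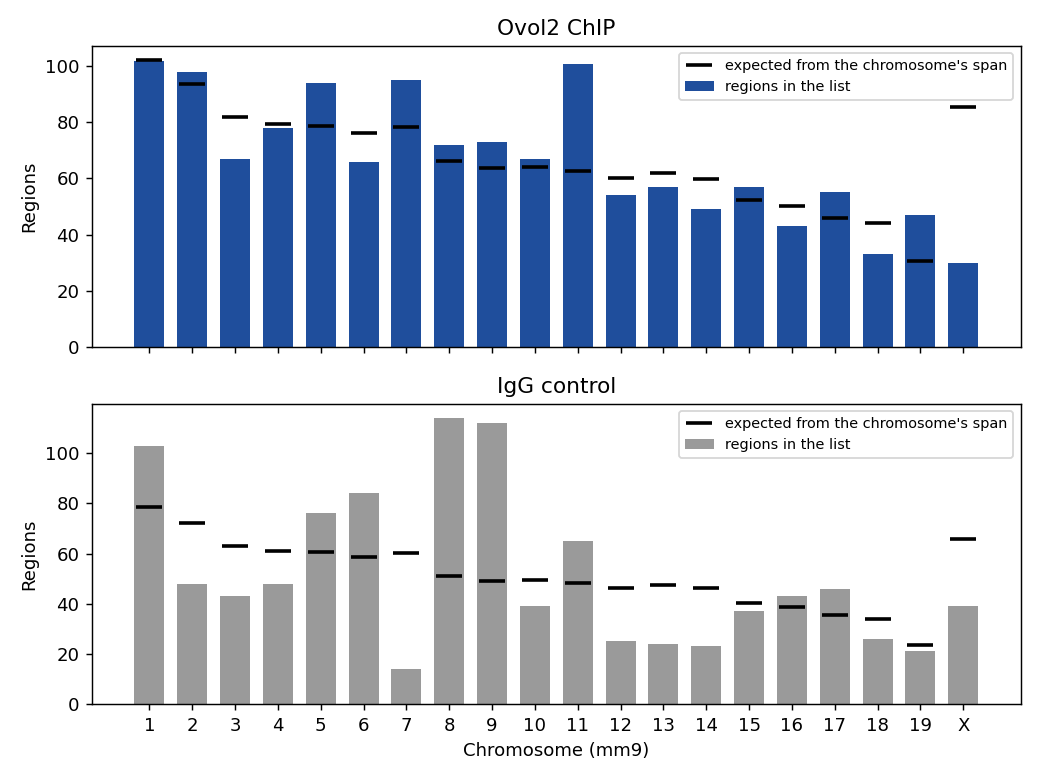
Number of called regions (vertical axis) on each autosome and X (horizontal axis), for the Ovol2 ChIP (blue) and the IgG control (grey), 1 library each, with black marks at the number expected from the span of the chromosome. Ovol2 regions exceeded the mark most on chromosome 11 (101 against 62.7), where IgG regions exceeded it too (65 against 48.3). Chromosome 7 held 14 IgG regions against 60.3 expected.

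Both lists were clustered along chromosomes. In the Ovol2 list 36 pairs of neighbouring regions were less than 10 kb apart, against a mean of 8.20 in 1000 random placements (4.39-fold, one-sided permutation p = 0.001, the smallest that the placements can give). In the IgG list there were 202 such pairs against 5.30 (38.1-fold, p = 0.001, likewise the smallest possible by permutation). The size of the excess depended on the distance chosen. For pairs under 1 kb apart it was 8.39-fold in the Ovol2 list and 232.7-fold in the IgG list. For pairs under 100 kb apart it was 2.42-fold and 4.99-fold. The IgG pairs included those among the 13 regions on chromosome Y, which the random placements left out. The IgG folds may therefore be too high. The densest IgG bin of 1 Mb was on chromosome 9 from 3 to 4 Mb, with 68 regions or 6.51% of the list. Chromosome 8 from 19 to 20 Mb held 41 IgG regions. Neither bin held any of the 1338 Ovol2 regions, which allows a share of up to 0.224% of the list, taking 3 counts as the limit that a count of 0 allows. Chromosomes 9 and 8 held 6.04 and 5.74 Ovol2 regions per 10 Mb, so a count of 0 in a bin of 1 Mb does not show avoidance. The first megabases of the chromosomes differed between the lists as a whole. Of the IgG regions on autosomes and X, 113 of 1030 (10.97%) started below 4 Mb, against 9 of 1338 Ovol2 regions (0.673%, Fisher's exact test, two-sided, p = 4.16e-32). These regions were clustered and not independent. With regions within 100 kb counted once, the counts were 16 of 787 IgG regions (2.03%) and 8 of 1162 Ovol2 regions (0.689%, Fisher's exact p = 0.011), and without chromosome 9 they were 14 of 743 (1.88%) and 8 of 1101 (0.727%, Fisher's exact p = 0.0291). The densest Ovol2 bin was on chromosome 11 from 120 to 121 Mb, with 7 regions of 2056 bp in the median, and held 3 IgG regions.

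The length of Ovol2 regions differed between chromosomes. Regions were longer than on the rest of the genome on chromosome 11 (median 1043 against 879 bp), chromosome 5 (1022 against 881 bp) and chromosome 8 (1004 against 882.5 bp), and shorter on chromosome 13 (746 against 895 bp). In two-sided permutation tests on 20 chromosomes the adjusted p-values were 0.002, 0.002, 0.0215 and 0.0147, and the other 16 chromosomes did not pass. Among 122 bins of 10 Mb with at least 5 regions, tested for high medians alone, the 2 that passed were the last bins of chromosome 11. The bin from 120 Mb had a median of 1911 bp over 10 regions, and that from 110 to 120 Mb 1326 bp over 13 regions (permutation p of the highest median, 0.002 and 0.048). Together the 23 regions from 110 Mb onwards had a median of 1597 bp and an interquartile range of 1249.5 to 2357 bp, against a median of 882 bp elsewhere. The same segment held 12 IgG regions against 4.75 expected from its span (exact binomial test, one-sided, p = 0.0036). The other 78 regions of chromosome 11 had a median of 945 bp, against 879 bp on the other chromosomes (two-sided permutation p = 0.0867).

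**Figure D3:**
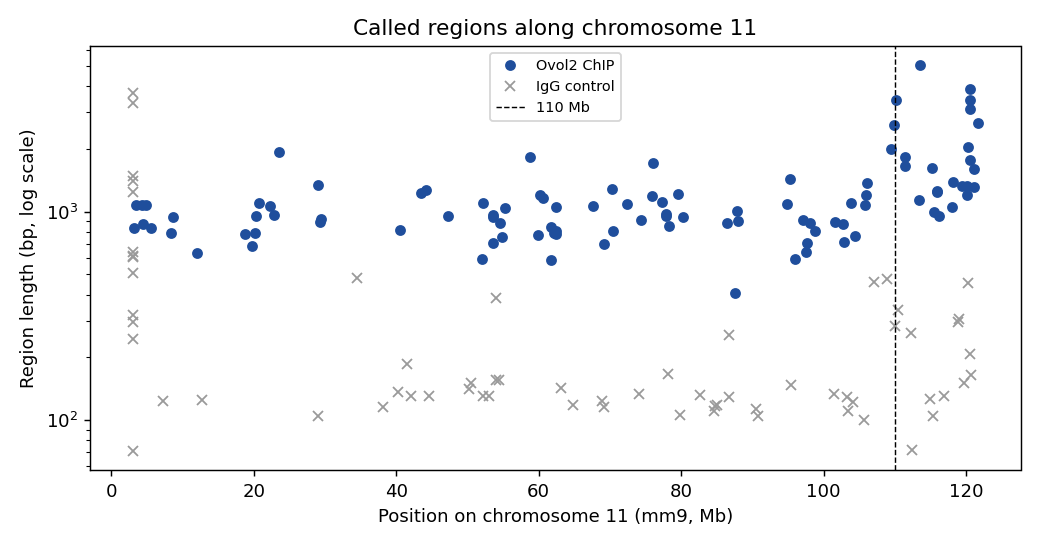
Length of called regions (vertical axis, bp, log scale) by position on chromosome 11 (horizontal axis, Mb of mm9), each point 1 region, for the Ovol2 ChIP (blue circles) and the IgG control (grey crosses), with a dashed line at 110 Mb. The 23 Ovol2 regions to the right of the line had a median of 1597 bp, against 945 bp for the 78 to the left.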

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

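With 1 library per antibody, no replicate could be left out. The alternatives on the Ovol2 list alone (its 671 longest regions, and the first 669 in the deposited order), on the IgG regions of higher score against the overlap, and on regions starting below 4 Mb were chosen after the data were seen. The 6 shared regions became 7 when regions within 1 kb counted as shared (permutation p = 0.001). A circular shift of each chromosome changes only the random placements, so 6 were shared as before (permutation p = 0.001). The setting with autosomes and X alone could test nothing, since no Ovol2 region lay on Y or the mitochondrial genome. Its random mean of 0.549 against 0.618 and its 10.9-fold excess (permutation p = 0.001) differed from the main values only through the random draws. The excess over random placement moved more than the count. It was 9.71-fold as reported, 4.42-fold within 1 kb (random mean 1.583) and 10.7-fold with the circular shift. With the 523 IgG regions of higher score 4 were shared (13.6-fold, permutation p = 0.002), and in the first 669 Ovol2 regions 5 were (15.4-fold, permutation p = 0.001). Among the 671 longest Ovol2 regions, 2 were shared against a random mean of 0.369, a 5.42-fold excess that missed the threshold with fewer regions (permutation p = 0.058). When 50% of the Ovol2 region had to be covered, 0 were shared and 100% lay outside; random placement then gave a mean of 0.024, as most IgG regions are too short to cover so much, so this rule tests no excess. By construction, the reduced lists held 671 and 669 Ovol2 regions and 523 IgG regions, and those Ovol2 lists stand for no stricter threshold. Counting regions within 100 kb once lowered the number of chromosomes that differ from 7 to 4, but chromosomes 2, 6, 7 and 8 kept their direction and their side of the threshold. The Ovol2 share of regions starting below 4 Mb minus the IgG share was -10.3 percentage points, -4.19 without chromosome 9, -1.34 with regions within 100 kb counted once, -1.16 also without chromosome 9 and -1.28 without chromosomes 9 and 11. Median lengths stayed within 1.5 times of the deposited lists under every alternative run. No stricter threshold by score could be applied to the Ovol2 list, and the alternatives on start sites, the hexamer and gene lists were not run. Depth is unknown and limits every statement on regions that are missing from a list.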

Other observations

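The tests below on IgG scores and on the link of Ovol2 length with IgG density were chosen after the values they use had been seen, and all hypotheses below were found and tested on the same 2 lists. On chromosome Y the IgG list held 13 regions, all between 2680630 and 2777182, with scores from 63.84 to 243.3, and the Ovol2 list held none. Region length fell along the deposited order of the Ovol2 list, from a median of 1069 bp in the first 133 regions to 767 bp in the last 133 (across regions, which are not independent replicates, Spearman's rho = -0.297, Pearson's r = -0.181, permutation p = 0.0001, the smallest it can be).

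Chromosomes with many IgG regions also had long Ovol2 regions. With IgG regions within 100 kb counted once, median Ovol2 length and IgG regions per 10 Mb were correlated over the 20 chromosomes (Spearman's rho = 0.756, permutation p = 0.00025, adjusted p = 0.00075 over 6 relations; Pearson's r = 0.701, permutation p = 0.00059, adjusted p = 0.0018). Most of the 6 relations were variants of this same correlation, so the adjustment does not correct for the search that found the pattern. Without chromosomes 6 and 8, the farthest from the median density, r was 0.663 and rho 0.712 (permutation p = 0.0023 and 0.0012). Without the distal part of chromosome 11, rho was 0.762. The low IgG share of chromosome 7 was not set by dense clusters elsewhere, since it remained with regions within 100 kb counted once (Fisher's exact test, adjusted p = 2.02e-05). A candidate explanation for the correlation is a chromosome-wide difference in background reads, such as unequal copy number in this cell line, that would lengthen Ovol2 regions and raise IgG calls alike; gene density, base composition and the calling settings stay open, as no sequence or read depth was used here. For the number of Ovol2 regions per 10 Mb in place of their length, rho with IgG density was 0.426 (permutation p = 0.065).

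The distal end of chromosome 11 held long Ovol2 regions. Without regions over 2 kb, the 16 left there had a median of 1319.5 bp against 880.5 bp elsewhere (permutation p = 0.0001, the smallest it can be), but the segment had been picked by its median length, which few long members hardly move, so this does not decide how much the longest regions contribute. The IgG list, which was not used to choose the segment, held 10.3 regions per 10 Mb there against 4.04 elsewhere (exact one-sided p = 0.0036). With IgG regions within 100 kb counted once there were 11 against 3.63 expected, or 3.03-fold. Raised local background could give both patterns, and extra copies of the segment in HC11 cells are a candidate source. A segment rich in open chromatin or in true Ovol2 sites is not excluded, and the region lists alone cannot tell these apart.

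The 6 shared regions exceeded the mean of random placement. When each Ovol2 region was moved by up to 1 Mb, a mean of 0.625 and at most 4 regions overlapped an IgG region, against 6 observed. This argues against a common crowding of both lists in parts of chromosomes much wider than 1 Mb. Such moves also break up crowding at shorter distances, so they do not test it, and both lists were clustered at under 10 kb. Only 1 of the 6 shared IgG regions had a score above the 90th percentile of the list. This does not decide whether strong IgG background was carried into the Ovol2 list, because the rule was set after the scores were seen. It also stays open whether the authors removed strong IgG regions from the Ovol2 list before deposit, which would leave weak ones as the overlap that remains.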
